A study of Tetrahymena thermophila with 6 samples.

How the data were processed

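Transcript levels were measured by RNA sequencing. Total RNA was taken from growing cultures of Tetrahymena thermophila strain CU428, a wild-type laboratory strain of this single-celled ciliate, and 6 libraries were made with Illumina protocols, per the labels' protocols. Each culture was grown in a peptone and yeast extract medium at 30 °C with shaking at 150 rpm and was split during exponential growth, per the labels' protocols. One part received 5 µg/ml cholesterol dissolved in ethanol and the other received the same volume of ethanol. The time between addition and harvest is not given in the sources used here. The labels describe 3 biological replicates per group.

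Per the file headers, each deposited file is an abundance table with the length, effective length, estimated count and TPM (transcripts per 1000000) of 26996 targets, each named by a locus tag. Per the submitters' processing notes, the tools named were CASAVA, FastQC 0.11.5, MultiQC 0.9, Trimmomatic 0.36, kallisto, DESeq2 1.16.1 and R 3.4.3. The kallisto version, its index, the genome build, the strand setting and the read length are not given in the sources used here. In each deposited file the TPM values sum to 1000000. The estimated counts are not scaled between libraries, and between 5.24% and 5.85% of them in each library are not whole numbers, because kallisto divides a read that fits several targets among them. Such a value occurred in at least 1 library for 2213 genes, and these genes are called genes that share reads. Of the target lengths, 99.2% are multiples of 3, so the targets are coding sequences and lengths are given as coding length. The deposited values use a comma as the decimal mark and were read that way.

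All 26996 locus tags matched the gene table of assembly JCVI-TTA1-2.2, but that table lists 0 genes with a symbol other than the locus tag, and the files hold no descriptions. Of the 36 gene lists in the plan, 35 rely on descriptions and could not be built. The remaining list holds 3 sterol-converting enzymes given by locus tag. Their names come from published characterisations of these loci, were part of the plan, and could not be checked against the files or the gene table, which do not pair tags with names. The gene table was used otherwise only to see which genes neighbour each other, and no coordinates are given because the build behind the files is not named.

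Estimated counts were rounded to whole numbers. Genes were tested if they reached the equivalent of 10 counts at the median library size in at least 3 libraries and 15 counts in all, which left 20424 genes. Libraries were scaled by the trimmed mean of M-values (TMM), and cholesterol was compared with control by limma 3.58.1 with voom weights and robust empirical Bayes moderation in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Counts per 1000000 (CPM) are scaled by the same factors. The plan fixed before the data were examined named a quasi-likelihood test on counts as the main test. For this comparison edgeR and DESeq2 were not used, because columns with decimal commas could not be checked automatically as counts and their unit was recorded as other. The limma-voom test, listed beforehand as a second test, took the place of the planned one after the data were examined. The gene list was tested with camera (preset inter-gene correlation 0.01), with camera using an estimated correlation, and with fry.

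On simulated data, 200 of 20424 genes were changed, with means, library sizes and spread estimated from the real libraries. The same steps recovered 77.6% of 1.5-fold, 95.5% of 2-fold and 100% of 4-fold changes. Of 196 calls, 7.1% were false, and data with no change gave 0 calls. Simulated genes of like abundance were given the same spread, so differences in spread between such genes were not carried over. The real comparison gave 4840 calls, far more than the 200 simulated changes. These rates therefore do not estimate its recovery or its false calls. Library totals lay between 25918230 and 39897259 estimated counts. The median standard error of a log2 fold change was 0.095, and it ranged from 0.235 in the least abundant quintile of genes to 0.059 in the most abundant one. The floor for a count of 0 was taken as 3 counts over the libraries of a group, which covers counting error only. All pairs of libraries within a group differed by more than counting noise, with a chi-square per gene between 3.42 and 10.01, so no pair was treated as one library deposited more than once. That each library is its own biological replicate rests on the labels.

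The genes given by tag were chosen by a rule of the same plan. Genes had to pass the threshold, average at least 1 CPM and show no overlap between groups, and were ranked by fold change. The plan allowed the 3 largest rises and the 3 largest falls whatever their description, and more among genes with a description. As no source pairs the tags with names, the rule was held to the 2 largest rises and the 2 largest falls, beside the 3 sterol enzymes. This cut was a departure from the plan. The 5 most abundant genes are described without their tags.

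The alternatives were other scalings (relative log expression, upper quartile, library totals), no low-count filter, a stricter one (a mean of 1 CPM and 3 libraries at 1 CPM), a correction for effective length, non-robust moderation, the replicate number as a block, removal of genes that take 1% of a library, limma on log2(TPM + 1) and log2(TPM + 0.1) over genes with a TPM of at least 1 in 3 libraries, a threshold of 0.01, and each library left out in turn. Added after the data were examined were limma with a mean-variance trend, removal of genes that share reads, library quality weights, and other filters and units for the correlations between libraries. Pairs of adjacent genes were compared with 10000 shuffles of the calls among genes of like abundance (20 bins), with Python 3.11.15.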

Results

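The data comprised 6 libraries of Tetrahymena thermophila from split cultures, 3 from parts given 5 µg/ml cholesterol and 3 from parts given ethanol alone. The ciliate makes no sterols of its own. It makes the triterpenoid tetrahymanol instead, and it takes up and converts sterols offered in the medium. The control libraries held 39897259, 28765422 and 31354391 estimated counts and the cholesterol libraries 39863446, 27540489 and 25918230. Between 23775 and 24269 of the 26996 annotated genes had an estimated count above 0 in a library.

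Libraries of one group resembled each other more than they resembled the other group. Pearson correlations of log2 CPM over the 20424 tested genes, which are not independent replicates, lay between 0.9924 and 0.9944 within groups and between 0.9761 and 0.9855 between groups. The first principal component of the 500 most variable genes held 79.5% of their variance and separated the 3 cholesterol libraries from the 3 control libraries, while the second held 7.8%.

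The study asked how transcript levels of the growing ciliate respond to cholesterol in the medium. The sterol-converting enzymes listed in the plan were examined first. The transcript of the C-7 sterol desaturase (TTHERM_00310640), a Rieske-type oxygenase that introduces the C-7 double bond into cholesterol, rose 6.4-fold, from 91.9 ± 8.72 CPM in control to 589 ± 61.8 CPM with cholesterol (SD, n = 3 each). The transcript of the C-5 sterol desaturase (TTHERM_01194720) rose 2.44-fold, from 9.46 ± 0.591 to 23 ± 0.719 CPM. The C-24 sterol de-ethylase (TTHERM_00438800) removes the ethyl side-chain group of plant sterols. Its transcript rose by 0.21 on the log2 scale, from 55.7 ± 1.97 to 64.4 ± 1.78 CPM.

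In limma-voom with Benjamini-Hochberg adjustment, the log2 fold changes of these genes were 2.68 ± 0.09 (SE, adjusted p = 3.03e-08) for TTHERM_00310640, 1.29 ± 0.07 (adjusted p = 3.87e-07) for TTHERM_01194720 and 0.21 ± 0.05 (adjusted p = 0.0139) for TTHERM_00438800. The 95% confidence intervals of the fold were 5.6 to 7.32 for the C-7 desaturase, 2.19 to 2.74 for the C-5 desaturase and 1.07 to 1.25 for the de-ethylase. All 3 members of this list rose, 0 fell, and the count was also 3 when adjusted over the list alone. As a set they stood above the other genes by camera in limma (p = 1.66e-05, 1 list tested), also with an estimated correlation (p = 0.0122), and fry gave p = 3.89e-07 for a shift in one direction. The estimated correlation was -0.362, from 3 genes only, so that camera run made no allowance for a positive correlation between them. The call for the de-ethylase was lost without control replicate 2 (adjusted p = 0.0771) or without cholesterol replicate 1 (adjusted p = 0.0528), and on the log2(TPM + 1) scale, where log2 fold changes moved by a median of -0.117 from those of the counts, its log2 fold change was 0.09 (adjusted p = 0.454). Over the 21 alternatives run in limma its adjusted p ranged from 0.00754 to 0.454. The calls for both desaturases passed the threshold under all 21 alternatives that were run.

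Among genes averaging at least 1 CPM, the largest falls were those of 2 abundant transcripts. TTHERM_01008630, with a coding length of 1968 bases, fell from 2500 ± 81.7 CPM in control to 17.1 ± 4.9 CPM with cholesterol (SD, n = 3 each). This was a 148-fold fall (95% confidence interval 110 to 200, limma adjusted p = 8.27e-07). TTHERM_00382150, with a coding length of 999 bases, fell 129-fold (81.4 to 204), from 1380 ± 90.8 to 11.1 ± 4.29 CPM (limma adjusted p = 2.47e-05). These 2 genes together took 0.396% ± 0.0151 of all counts in control and 0.0028% ± 0.0008 with cholesterol (SD, n = 3 each).

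The largest rises among these genes were those of transcripts with 0 or few counts in control. TTHERM_00030420, with a coding length of 495 bases, had 0 counts in each control library and 2079, 1763 and 1691 counts in the cholesterol libraries, or 61.6 ± 6.75 CPM (SD, n = 3). Against the floor of 3 counts over the control group, equal to 0.0295 CPM, it was at least 2090-fold higher with cholesterol (limma adjusted p = 1.31e-08). TTHERM_00085010, with a coding length of 1260 bases, had 9, 7 and 7 counts in the control libraries and 1901, 1255 and 1113 in the cholesterol libraries. It rose 193-fold (95% confidence interval 132 to 281, limma adjusted p = 3.5e-09), and its log2 fold change of 7.59 was 4.85 on the log2(TPM + 1) scale and 6.90 on the log2(TPM + 0.1) scale, where the added constant lowers the change of a gene near 0 in one group. The sources used here do not pair the tags of these 4 genes with names. None of the 7 named genes had a fractional estimated count, the sign of shared reads, in any library.

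**Figure D1:**
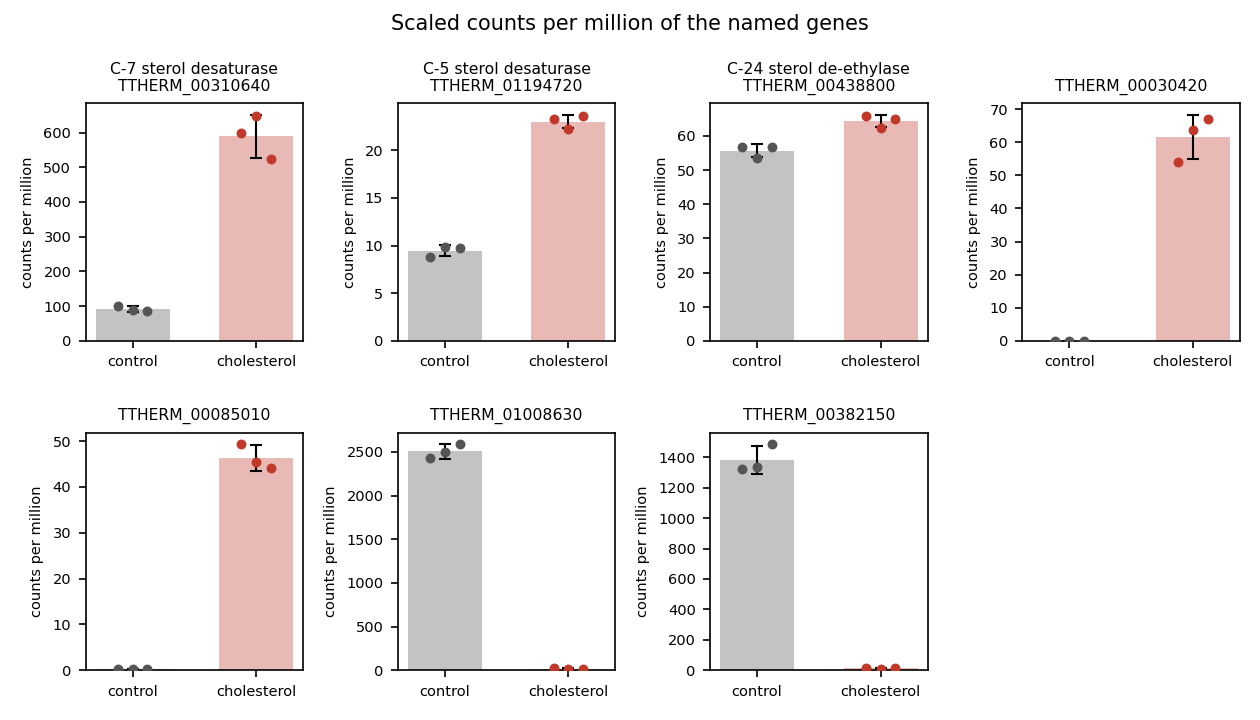
Scaled CPM (vertical axes, linear and starting at 0) of the 7 named genes in control and cholesterol libraries, with points for libraries, bars for means and whiskers for SD (n = 3 per group). The C-7 sterol desaturase stands at 91.9 CPM in control and 589 CPM with cholesterol, and TTHERM_01008630 at 2500 and 17.1 CPM.

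Across the transcriptome, 2401 genes were higher and 2439 lower with cholesterol, or 11.76% and 11.94% of the 20424 genes tested by limma at an adjusted p under 0.05. Most changes were small. Of the higher genes, 1600 changed by less than 1.5-fold, 518 by 1.5- to 2-fold, and 283 by at least 2-fold. Of the lower genes, 1707 changed by less than 1.5-fold, 439 by 1.5- to 2-fold, and 293 by at least 2-fold. Rises of at least 4-fold were seen in 40 genes and falls of at least 4-fold in 39 genes, among them 5 rises and 6 falls of 16-fold or more. The genes at least 2-fold higher took 0.692% ± 0.0645 of all counts in control and 1.88% ± 0.144 with cholesterol, and the genes at least 2-fold lower took 1.55% ± 0.103 and 0.402% ± 0.0425 (SD, n = 3 each). These genes were picked on the same libraries, so the shares describe the size of the change and do not test it.

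The count of lower genes was 1600 without control replicate 2 and 1526 without cholesterol replicate 2. With library totals in place of TMM, 1846 genes were higher and 3490 lower, while relative log expression scaling gave 2490 and 2341 and upper-quartile scaling 2479 and 2356. The median log2 fold change was -0.004 with TMM and moved by a median of 0.007 with each of these last scalings. All of them place the typical gene at about no change, so their near-equal splits are not independent of each other. In the TPM fits, which also differed in filter, genes tested (18048) and weights, the split moved too. On the log2(TPM + 1) scale 1000 were higher and 3287 lower, and on the log2(TPM + 0.1) scale, where log2 fold changes moved by a median of -0.133, 987 were higher and 3236 lower. The counts of genes at least 2-fold higher and lower, 283 and 293, were 94 and 204 on the log2(TPM + 1) scale and 147 and 305 on the log2(TPM + 0.1) scale.

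**Figure D2:**
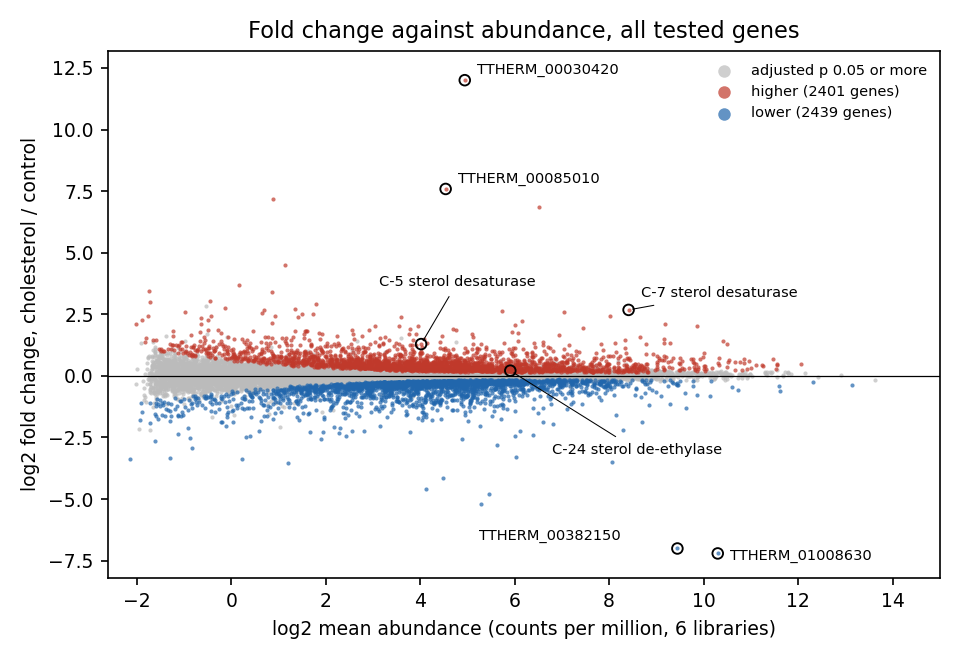
Log2 fold change of cholesterol over control (vertical axis) against log2 mean CPM over the 6 libraries (horizontal axis) for the 20424 tested genes, with red points for the 2401 higher genes, blue for the 2439 lower genes, grey for the rest, and circles around the 7 named genes. TTHERM_00030420 is drawn at its fitted value, which depends on the small count that the model adds to its 0 control counts.

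Changes were found at every abundance. In the most abundant quintile of genes, at 39.1 CPM or more, 742 genes were higher and 633 lower, which is 33.7% of that quintile. In the least abundant quintile, at 2.39 CPM or less, 263 were higher and 205 lower, or 11.5%. Changes of at least 2-fold made up 2.2% of the most abundant quintile and 5.56% of the least abundant one. The median standard errors of the log2 fold change were 0.059 and 0.235 in these quintiles, so the smallest detectable change was larger for rare transcripts. The 2-fold limit was set on fitted values, which are less precise for rare transcripts. These shares therefore do not compare the size of the response between quintiles. With the stricter low-count filter, 207 genes were at least 2-fold higher and 229 at least 2-fold lower. Of the 5 most abundant genes, which ranged from 5095 to 12604 CPM, 2 were lower with log2 fold changes of -0.36 and -0.25 and limma adjusted p-values of 0.00755 and 0.0179. The other 3 did not pass the threshold, with log2 fold changes of -0.17, 0.02 and -0.04. Complete loss or gain of a transcript was rare among the called genes, which had to pass the low-count filter. Of the called genes, 1 had 0 counts in all 3 control libraries (TTHERM_00030420) and 0 had 0 counts in all 3 cholesterol libraries.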

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

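The fits with a mean-variance trend, without genes that share reads and with library quality weights, and the settings for correlations between libraries, were chosen after the data were examined. Quasi-likelihood (edgeR) and DESeq2 fits, with and without the block, were planned and not run, because count columns with decimal commas could not be checked automatically as counts. The labels say that cultures were split between the groups but not that a number marks one culture, so numbers were not taken as pairs. Deviations of same-numbered libraries correlated at 0.09, -0.04 and 0.21, and 3 of 6 libraries correlated best with their own number. So few libraries leave pairing open. With the replicate block more genes passed (2955 higher, 2805 lower), 286 were at least 2-fold higher and 288 at least 2-fold lower, and no named call changed. The counts of higher and lower genes, 2401 and 2439, moved by over 1.5 times under these settings: an adjusted p under 0.01 gave 1396 higher and 1276 lower, log2(TPM + 1) gave 1000 higher, log2(TPM + 0.1) gave 987 higher, and leaving out control replicate 2 or cholesterol replicate 2 gave 1600 and 1526 lower. The genes at least 2-fold higher and lower, 283 and 293, were 94 and 204 with log2(TPM + 1) and 147 and 305 with log2(TPM + 0.1). Of the 4840 calls, 3238 were shared with the log2(TPM + 1) fit, in which 315 of them were not tested. TPM values are not rescaled between libraries, and log2 fold changes moved by a median of -0.117 and -0.133 in these 2 fits. The cause of the remaining difference was not tested. Leaving out each library in turn gave 1651 to 2488 higher, 1526 to 2371 lower, 246 to 338 at least 2-fold higher and 231 to 336 at least 2-fold lower genes. The sterol list held 3 higher members, or 2 under the settings that lost the C-24 de-ethylase, and its camera p stayed between 7.53e-06 and 6.36e-05 with each library left out. TTHERM_00438800 lost its call in 5 of 21 alternatives (adjusted p up to 0.454, log2 fold change 0.09 to 0.21), including the threshold of 0.01, and the other 6 named genes kept theirs in all 21. The mean within-group correlation, 0.9933, was 0.9865 without a low-count filter, 0.9947 with the stricter one and 0.9951 on the log2(TPM + 1) scale. Fold changes of rare transcripts were the least precise (median standard error 0.235 in the least abundant quintile).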

Other observations

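The tests on neighbouring genes, coding length and read sharing were chosen after these patterns were seen in the data. Genes that changed by at least 2-fold lay next to each other more often than in shuffles. Of 16735 adjacent pairs of tested genes, 26 pairs were both at least 2-fold higher with cholesterol and 35 pairs both at least 2-fold lower, against means of 3.06 and 3.31 in 10000 shuffles. A pair with one gene higher and its neighbour lower occurred 2 times, within the 95% range of the shuffles, 2 to 12. Over all called genes, of any fold, the excess was smaller relative to the shuffles: 807 pairs changed in one direction against a mean of 501.07, and 355 in opposite directions against 499.98 (95% range 461 to 540). Runs of at least 2 such neighbours held 48 of the 283 higher genes, or 17.0%, and 59 of the 293 lower genes, or 20.1%. The longest run held 3 genes among the higher and 7 among the lower genes, and without cholesterol replicate 3 the count of pairs in one direction was 63.

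This clustering was noticed in the data and tested on the same data. It exceeded shuffles among genes of like abundance, with 61 pairs in one direction against at most 18 (one-sided permutation p = 0.0001, the smallest that 10000 shuffles can give). Reads shared between near-identical neighbours do not account for it alone, since 47 pairs were counted against at most 16 after genes that share reads were left out. Transcripts running on into a neighbour stay open: in 40 pairs, against at most 15 in shuffles, the smaller change in CPM was at least 10% of the larger one, but that limit was assumed and the size of run-on was not measured. No biological explanation of the clustering was tested, and strand and sequence were not used here.

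Genes with short coding sequences had higher fold changes, as the median log2 fold change of the shortest quintile, 758 bases or less, lay 0.116 above that of the longest quintile (bootstrap 95% interval 0.106 to 0.128), and genes are not independent replicates. Leaving out genes that share reads gave 0.126, which goes against these genes as its source. Without cholesterol replicate 3 the difference was 0.033, so the trend may rest largely on that library. It had the longest fragments (225.5 bases, against 196.4 to 210.8 in the others) and its short genes lay 0.21 above its long genes, relative to the mean of the 6 libraries on the log2 scale, while the other cholesterol libraries, at -0.061 and 0.008, lay within the range of the controls, -0.119 to 0.021. Fragment length stays open, because correcting for effective length (difference 0.156) can only raise short genes where fragments are longer, and an effect of cholesterol on short genes stays open and untested. The shortest quintile held 491 higher and 218 lower genes, and the longest 414 and 526. The quintile of 1848 to 3030 bases had the lowest median log2 fold change, -0.054, with 409 higher and 687 lower genes. How far this trend shaped the counts of small changes was not tested.

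Genes that share reads were more common among higher than among lower genes, at 256 of 2401 (10.7%) against 98 of 2439 (4.0%), with 7.5% among genes that did not pass the threshold (two-sided Fisher's exact test across genes, higher against lower, odds ratio 2.85, p = 2.71e-19). Genes of one family are not independent, so this p is too small.

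The real grouping was compared with the other ways of splitting the 6 libraries into 3 and 3, which make 10 splits with the real one. With limma-voom, the real split gave 2401 higher, 2439 lower, 283 at least 2-fold higher and 293 at least 2-fold lower genes, and the highest of the other splits gave 0 for each, so 1 split of the 10 reached the real value. With 10 splits the share cannot fall under 0.1, and this comparison is too small for a share under 0.05. Each other split also mixes both groups on both sides, so the difference between groups adds to its spread. The 0 calls of those splits therefore do not estimate the false calls of the real one.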
